A study of Mus musculus with 4 samples.

How the data were processed

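Single-cell RNA of mouse pancreatic islet cells was measured in 4 libraries, 1 for each group named in the sample labels: normal control, early db/db, late db/db and late db/db with intervention. The labels give an age of 98 days for 3 of the groups and 70 days for early db/db. The labels' protocol names 10x Genomics 3′ chemistry and Illumina sequencing. The number of mice pooled in each library is not given in the sources used here. All 4 genotype labels read db/db on C57BL/KsJ, the control's included, while the growth protocol names C57BL/6 as well as db/db mice, and no genotype was read from the data. The intervention is not described in the sources used here, apart from an abbreviation that they do not expand. The deposited matrix of early db/db carries a name that reads as a second control, and the sample label was followed.

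The deposited matrices hold UMI counts (counts) for 30905 genes per cell barcode, as whole numbers with no normalization, and the gene list is identical in the 4 libraries. Per the file headers, the matrices were written by Cell Ranger software version 3.0.0. The processing notes with the samples name the genome build mm10, CASAVA 1.8, Cell Ranger and Seurat, without versions for the last 2 and without a role for Seurat. The annotation release used for counting is not given in the sources used here. Every barcode held at least 500 UMIs, so barcodes with fewer UMIs had been left out before deposit, by a rule not given in the sources used here. Gene positions were taken from GENCODE M21 (GRCm38), by gene identifier.

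Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Scrublet in scanpy 1.11.5 scored doublets in each library. Its automatic threshold marked 5 of 5115 cells (0.0978%) of the intervention library, too few to have worked, so the highest scores were removed in every library at the rate of 0.8% per 1000 cells. That rule was set after seeing the data. It removed 171, 184, 318 and 209 cells of the control, early, late and intervention libraries, and 4458, 4616, 5983 and 4906 cells were kept.

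The kept cells of the 4 libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken from those other than hormone, mitochondrial and ribosomal protein genes, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) followed. Each cluster took the class with most of its listed markers among its 25 leading genes by fold, with a pseudocount of 0.5. A cluster stayed unnamed when it rested on under 3 raised markers (at least 2-fold over the median of the other clusters, in at least 10% of cells), when markers of another class led its 10 leading genes, or when its UMI count was low and none of its own markers was among those 10. The ranking by means of log values, and the second clustering of clusters led by cell cycle genes, were set after seeing the data. Names such as beta-like therefore rest on clusters rebuilt here and not on an annotation from the authors.

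For each class, UMIs were summed over the cells of a library. CPM values used as denominator the library's sum over genes other than the mitochondrial genes and 7 hormone genes (Ins1, Ins2, Iapp, Gcg, Sst, Ppy and Pyy). A gene entered a comparison with at least 50 CPM in the higher library and at least 50 UMIs in both together, and it was counted when the ratio was at least 2-fold. Ratios carry exact conditional binomial 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. These intervals cover counting error only. Each group is 1 library, so no test was run, no spread between animals could be estimated and no replicate check was possible. Where a library held 0 UMIs of a gene, the ratio was bounded against a floor of 3 UMIs in that library's sum.

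The 5 comparisons of beta-like cells were late db/db with control, early db/db with control, late with early db/db, and the intervention with late db/db and with control. Early db/db differs from the other libraries in age as well as group. The same sums were made for alpha-, delta-, endothelial- and macrophage-like cells where both libraries held at least 100 cells. For the position of the intervention between late db/db and control, the control and late cells were split at random, so that one part chose the genes and the other gave the distance. The position used log2 values with a pseudocount of 1 UMI. Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs, with shallower cells left out.

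The comparisons, thresholds, markers and 24 gene lists were fixed before the data were examined. The lists were beta cell transcription factors, glucose sensing and insulin exocytosis, prohormone processing and granule proteins, dedifferentiation markers, disallowed genes of beta cells, endoplasmic reticulum chaperones and the unfolded protein response, the amino acid and integrated stress response, cytosolic tRNA synthetases, antioxidant genes and metallothioneins, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cytosolic ribosomal proteins, proteasome subunits, glycolysis, carbohydrate response and lipogenesis, cholesterol synthesis, fatty acid oxidation, interferon response and MHC class I, NF-kappaB targets and chemokines, cell cycle, pro-apoptotic and p53 genes, autophagy and lysosome, immediate early and heat shock genes as a sign of dissociation stress, and the Reg family. A list's median log2 ratio over its measured members was set beside the medians of 10000 random lists of the same size matched on mean expression, as a percentile that describes these libraries only. Lists with under 5 measured members have no percentile.

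Genes are named by a rule fixed at the same time. It takes the hormone genes and Lepr, then the 8 largest ratios in each direction among genes at least 2-fold apart under 3 scalings. Mitochondrial, ribosomal protein and unnamed model genes, markers of other classes and genes at least 5-fold higher in another named class of at least 50 cells were left out of those. It also takes up to 4 members of each list with the largest ratios, and the 5 largest ratios in each direction for other classes. The scalings were the denominator above, all UMIs as denominator, and TMM factors from edgeR 4.0.16 in R 4.3.3.

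The alternatives for the cell shares were no filter on cells, a stricter filter (2000 UMIs, 1000 genes and 10% mitochondrial UMIs), doublets kept, Leiden resolutions of 0.5 and 2, 4000 variable genes and each library clustered alone. For the gene ratios they were both other scalings, minimums of 10 and 200 CPM, no filter on low counts, a mean over cells, thinned cells, free RNA subtracted, genes high in another class left out, and folds of 1.5 and 3, beside the stricter filter, doublets kept and each library clustered alone. The position was also taken from whole libraries and at 1.5-fold, and shares of cells with a UMI unthinned and after thinning to 5000 UMIs. Free RNA was scaled on the Ins1 and Ins2 share of endothelial- and macrophage-like cells, which came to 12.8%, 6.57%, 2.36% and 12.8% of the share in all kept cells of the control, early, late and intervention libraries. Scrublet's automatic thresholds, endocrine cells as the only denominator, leaving out beta-like clusters with a median of at least 90000 UMIs, requiring 2-fold in all 3 scalings and taking Stmn1 without the beta-like clusters that have it among their leading genes were chosen after seeing the data.

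The steps were tested on simulated counts with 200 changed genes in each of the 5 comparisons. Genes changed 3-fold or 6-fold were called at least 2-fold apart in the right direction in 100% of cases in each comparison, and genes changed 1.5-fold in 0%. The intervals held the true ratio for 95.0% of genes for late db/db with control, 95.6% for early db/db with control, 95.5% for late with early db/db, 95.0% for the intervention with late db/db and 94.8% for the intervention with control. Of unchanged genes, 0 were called. Among 200 simulated lists of 20 unchanged genes, 5 fell outside the central 95% of random lists, and a shifted list reached percentile 100. The simulation holds counting error only, with no difference between animals.

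Sums and intervals were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Sequence reads, spliced and unspliced counts and cell type labels from the authors were not analysed here. Barcodes that failed the filter entered no comparison.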

Results

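UMIs were counted in single cells of mouse pancreatic islets, with 1 library for each of 4 groups: normal control, early db/db, late db/db and late db/db with intervention. The labels give an age of 70 days for early db/db and 98 days for the others. The sums over all barcodes were 166034254 UMIs in the control, 125498999 in early db/db, 120934779 in late db/db and 157952234 in the intervention library. After filtering, 4458, 4616, 5983 and 4906 cells were kept in that order, with medians of 25984, 14544.5, 6190 and 26430.5 UMIs per cell. The barcodes had numbered 6143, 6655, 7162 and 6800. The genotype label reads db/db on C57BL/KsJ for the control as well, while the growth protocol also names C57BL/6 mice, so the strain of the control is not settled by the labels. What the intervention was is not given in the sources used here, apart from an abbreviation that they do not expand. With 1 library per group there was no replicate check and no test, and the 95% intervals given here cover counting error only. Differences are therefore described as higher or lower, and cannot be split between the group, the animals and the library.

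Lepr, the leptin receptor gene that the db allele disrupts, had 41 UMIs in the kept cells of the control, 109 in early db/db, 126 in late db/db and 31 in the intervention library. In beta-like cells it had 3, 0, 2 and 0 UMIs, too few for a ratio. Counts at the 3′ end of transcripts check nothing about the db allele.

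Insulin-producing beta-like cells were the largest class in the control, early db/db and intervention libraries, and lymphocytes outnumbered all other cells in the late db/db library. Beta-like cells were 50.8% of kept cells in the control (95% interval 49.3 to 52.2), 32.4% in early db/db (31.0 to 33.7), 13.6% in late db/db (12.8 to 14.5) and 69.2% with the intervention (67.8 to 70.5). B-like cells were 31.6% and T- and NK-like cells 34.4% of the late library, against 0.247% and 0.269% in the control, 5.48% and 2.45% in early db/db, and 0.163% and 0.489% with the intervention. Dendritic-like cells numbered 117 in late db/db, 5 in early db/db, 3 with the intervention and 0 in the control. Early db/db also held more exocrine cells, with 2.86% acinar-like and 3.51% duct-like against 0.0673% and 0.0897% in the control.

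Among alpha-, beta- and delta-like cells alone, a denominator chosen after the lymphocytes were seen, the beta-like share was 58.4% in the control (56.8 to 59.9), 56.5% in early db/db (54.6 to 58.4), 73.5% in late db/db (70.8 to 76.1) and 79.6% with the intervention (78.4 to 80.8). The order of late db/db and control therefore turned with the denominator. Glucagon-producing alpha-like cells were 28.2%, 31.8%, 14.4% and 13.8% of these endocrine cells in the same order, and somatostatin-producing delta-like cells 13.4%, 11.7%, 12.1% and 6.60%. Macrophage-like cells were 2.0%, 3.99%, 2.02% and 1.98% of kept cells, and endothelial-like cells 4.60%, 9.21%, 2.07% and 4.53%. No cluster was named gamma-, neutrophil-, mast-, mesothelial- or erythroid-like, which is no sign that such cells were absent. Clusters left without a name held 3.25%, 4.81%, 5.06% and 1.69% of kept cells. Of these, cluster 3 held 145, 38, 33 and 71 cells and was led by the pancreatic polypeptide genes Ppy and Pyy, which are gamma cell markers.

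**Figure D1:**
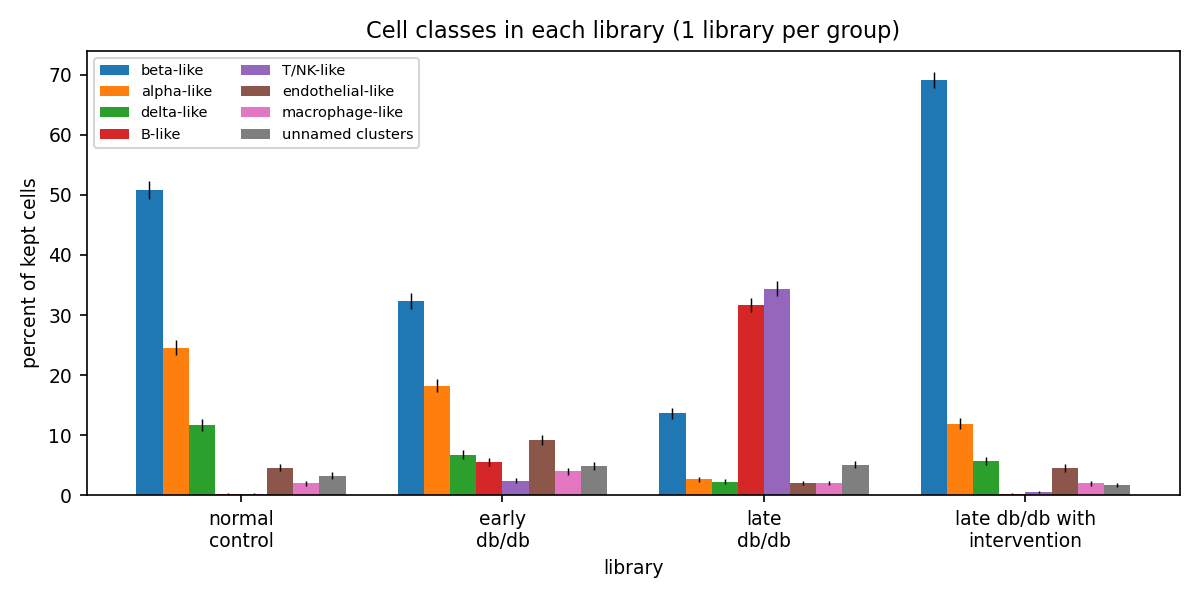
Percent of kept cells in each cell class (vertical axis) in the 4 libraries, with bars for the share and lines for its exact 95% interval. Beta-like cells range from 13.6% in late db/db to 69.2% with the intervention, and T- and NK-like cells reach 34.4% in late db/db.

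Insulin message took a lower share of beta-like UMIs in the db/db libraries than in the control, and amylin message a higher share. Ins1, the rodent-specific insulin gene, took 18.2% of all beta-like UMIs in the control, 4.75% in early db/db, 4.15% in late db/db and 10.5% with the intervention. Ins2, the insulin gene shared with other mammals, took 46.8%, 42.5%, 37.5% and 35.7%, so the ratio of Ins1 to Ins2 was 0.388, 0.112, 0.111 and 0.295. Iapp, which encodes amylin, took 3.91%, 12.1%, 11.7% and 12.7%. The 7 hormone genes together took 69.0%, 59.5%, 53.5% and 59.1%, which is why the ratios of all genes use a denominator without them. Beta-like cells numbered 2263, 1494, 816 and 3393, with medians of 49489, 56136, 86868 and 41378 UMIs per cell. Since these medians differed, the shares do not give the amount of message per cell. The cluster holding the largest part of the class differed between the libraries. Cluster 2 held 2125 of the control's cells, cluster 15 held 1041 of early db/db, cluster 14 held 454 of late db/db and cluster 4 held 1622 of the intervention library.

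Late db/db against control, both 98 days old, compares diabetic with control islets. Beta-like cells of late db/db held high levels of the peptide hormone genes Cck and Gast and of Aldh1a3, which encodes a retinaldehyde dehydrogenase known from dedifferentiating beta cells, and low levels of the beta cell regulator Mafa and of Slc2a2, which encodes the glucose transporter GLUT2. Cck (ENSMUSG00000032532, GRCm38 chromosome 9, 121489824 to 121495694) stood at 1931 CPM against 0.0637 CPM, from 54304 and 2 UMIs, a log2 ratio of 14.89 (13.03 to 17.93). Aldh1a3 (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517) stood at 427 CPM against 2.42, a log2 ratio of 7.46 (7.14 to 7.81), and Gast at 654 against 1.94 CPM, or 8.39 (8.03 to 8.78). Mafa (ENSMUSG00000047591, chromosome 15, 75745490 to 75748228) stood at 32.8 CPM against 1087, a log2 ratio of -5.05 (-5.15 to -4.96). Slc2a2 (ENSMUSG00000027690, chromosome 3, 28697903 to 28731359) stood at 39.4 CPM against 933, or -4.56 (-4.65 to -4.48). The log2 ratio was -2.79 for Ins1, -0.98 for Ins2 and 0.92 for Iapp.

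The other genes with the largest positive ratios were Tm4sf20 with a log2 ratio of 10.80 (8.32 to 16.11) on 1 control UMI, Pianp with 9.61, the casein gene Csn3 with 7.87, C1qtnf1 with 7.21 and the acetylcholinesterase gene Ache with 5.67. On the lower side, the MHC class I gene H2-Q2 (ENSMUSG00000091705, chromosome 17, 35342242 to 35346762) had 1 UMI in late db/db against 3253 in the control, a log2 ratio of -11.51 (-16.81 to -9.03). Npy, the gene of neuropeptide Y, had 0 UMIs against 1589 and was at least 475-fold lower. The sialoadhesin gene Siglec1 had a log2 ratio of -8.71, the cation channel gene Trpm5 -7.75, Fam151a -6.98, the cytochrome oxidase subunit gene Cox6a2 -6.11 and Adam32 -5.72. Among the other islet hormones, Gcg was at -1.77, Sst at -2.37, Ppy at 1.01 and Pyy at 0.04, but Ppy turned to -0.76 with the stricter cell filter and Gcg to 11.50 after free RNA was subtracted. So large a move means that the subtraction took away nearly all Gcg of the control, where free RNA was scaled at 12.8% against 2.36% in late db/db. The value of 11.50 therefore measures no fold.

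Genes of beta cell identity and stimulus coupling lay low as groups in late db/db. Of 10 measured beta cell transcription factor genes, 5 were at least 2-fold lower and 0 higher, with Nkx6-1 at -1.36, Neurod1 at -1.20 and Foxa2 at -1.13 beside Mafa. Their median log2 ratio was -0.99 (-0.33 with all UMIs as denominator, -0.67 with TMM), and 0.02% of random matched lists lay lower. Relative to the median of all genes it was -0.69 under each of the 3 scalings. The other scalings raise all ratios of this comparison, so the counts of lower genes in lists apply to the first denominator. Of 18 glucose sensing and exocytosis genes 9 were lower and 0 higher, with a median of -1.10 (-0.81 relative to all genes, percentile 0); they include the exocytosis gene Sytl4 at -3.55 and the zinc transporter gene Slc30a8 at -3.39. Prohormone processing and granule genes went both ways, with 7 of 15 higher, such as Vgf at 3.95, Chgb at 2.21 and Pam at 1.56, and 2 lower. Their median was 0.19 (0.48 relative to all genes, 1.08 with all UMIs as denominator, percentile 22.3). Of 5 measured dedifferentiation markers 4 were higher, Cd81 at 3.27 among them (median 7.46, percentile 100). The list has 10 genes, and the rest did not enter. Cck, Gast and Aldh1a3 entered through their late db/db level alone, which pulls this median and percentile upward.

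Protein folding genes leaned higher, with 3 of 26 endoplasmic reticulum and unfolded protein response genes at least 2-fold higher and 1 lower. Creld2 stood at 1.76, the co-chaperone gene Dnajc3 at 1.26 and Sdf2l1 at 1.15, while the oxidoreductase gene Ero1lb, which is enriched in beta cells, stood at -2.21 (median 0.36, 0.66 relative to all genes, percentile 94.8). Ribosomal protein genes lay above 0 in 78 of 79 cases, none of them by 2-fold (median 0.53, percentile 93.2). All 12 measured mitochondrially encoded genes lay below 0, mt-Nd5 at -1.01 among them (median -0.70, -0.41 relative to all genes, -0.08 with all UMIs as denominator, percentile 0). Among 15 antioxidant genes the peroxidase gene Gpx3 at 2.38 and Prdx4 were higher, and the metallothionein genes Mt2 at -1.37 and Mt1 at -1.29 lower, around a median of -0.03 that was 0.72 with all UMIs as denominator. Of 6 carbohydrate response genes, Arrdc4 at 2.15 was higher, and the transcription factor gene Mlxipl at -1.57 and the ATP citrate lyase gene Acly at -1.04 were lower (median -0.62). Fatty acid oxidation had 2 of 7 genes lower, Hadh at -1.74 and Acadl at -1.35 (median -0.70).

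The remaining lists held few genes that far apart. The counts higher and lower were 0 and 1 of 14 for the amino acid and integrated stress response (Atf5 at -1.71), 0 and 1 of 13 for tRNA synthetases (Gars at -1.50), 1 and 0 of 70 for nuclear oxidative phosphorylation (Ndufa1 at 1.91), and 0 and 0 of 31 for the proteasome. They were 0 and 1 of 9 for glycolysis (Pfkl at -1.18), 0 and 1 of 10 for cholesterol synthesis (Srebf2 at -1.25), 1 and 0 of 15 for autophagy and lysosome (Ctsl at 1.16) and 1 and 0 of 14 for immediate early and heat shock genes (Klf6 at 1.71). In lists with under 5 measured genes, the antigen presentation genes H2-D1 and Tapbp stood at 2.19 and -0.89, with H2-K1 also lower, the NF-kappaB genes Nfkbia and Nfkb1 at -1.37 and -1.08, the cell cycle genes Stmn1 and Hmgb2 at -3.71 and -1.23, and the apoptosis genes Bax and Bad at -0.44 and -0.13. Of the control's Stmn1 UMIs, 84.0% lay in 28 cells of clusters 9 and 33, and without these clusters Stmn1 stood at -1.60 (-1.93 to -1.28). Of the genes named for these lists, Gpx3, Acadl, H2-K1, Nfkbia, Stmn1, Hmgb2 and Klf6 were at least 5-fold higher in another cell class. Of the 18 disallowed genes and the 7 Reg genes 0 reached 50 CPM, in this comparison and in the other 4.

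In all, 188 genes were at least 2-fold higher and 488 lower of 4189 that entered. The median of all genes was -0.29 here, 0.36 with all UMIs as denominator and 0.03 with TMM, so 27.8%, 90.9% and 72.2% of the genes so far apart were higher under the 3 scalings. These percentages, here and below, apply the minimum of 50 CPM anew in each scaling, which changes the genes that enter. The same holds for every list median given under another scaling. Such a median can therefore move by more than the shift common to all genes. The interferon median, for one, was -0.89 here and 0.85 with all UMIs as denominator. Of the 188 higher and 488 lower genes counted first, 188 and 129 stayed at least 2-fold apart under all 3 scalings. Both other scalings raise every ratio of this comparison, so the higher genes had to stay and only lower ones could drop out. With one of the other scalings the list medians changed sign for amino acid, tRNA synthetase, antioxidant, oxidative phosphorylation, proteasome, cholesterol, interferon, NF-kappaB and apoptosis genes.

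Early db/db against control shows the same comparison at a younger age, 70 against 98 days, so age differs as well as group. It uses the control library of the late comparison, so features of that library alone enter both. Genes named for late db/db lay far from that control, with Cck, Gast and Aldh1a3 high and Mafa and Slc2a2 low. Cck stood at 2371 CPM, a log2 ratio to the control of 15.18 (13.33 to 18.23), Csn3 at 8.46, Gast at 7.46 and Aldh1a3 at 7.21 (6.89 to 7.56). Tm4sf20 stood at 10.70, again on 1 control UMI, Pianp at 9.53, C1qtnf1 at 7.02, Ache at 5.80 and the glucose cotransporter gene Slc5a10 at 5.35. Lower genes included H2-Q2 at -10.59 (-13.63 to -8.73) on 2 early UMIs, Npy at -9.55 (-12.60 to -7.70) also on 2, Siglec1 at -8.79, Trpm5 at -7.98, Fam151a at -6.55, Mafa at -5.22, Cox6a2 at -5.07, Adam32 at -4.66 and Slc2a2 at -4.32. Ins1 stood at -2.39, Ins2 at -0.60 and Iapp at 1.17, and the other islet hormones Gcg, Sst, Ppy and Pyy at -0.91, -0.51, 1.05 and 0.17, with Ppy at -0.79 under the stricter filter.

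Beta cell transcription factor genes were lower in 5 of 10 cases and higher in 0, with Nkx6-1 at -1.61 and Neurod1 at -1.34. Their median was -0.98 (-0.74 relative to all genes, -0.52 with all UMIs as denominator, percentile 0.02). Glucose sensing and exocytosis genes were lower in 11 of 18, with Slc30a8 at -3.40 and Sytl4 at -3.31 (median -1.37, percentile 0). Of 6 measured dedifferentiation markers, from a list of 10, 5 were higher (median 6.28, percentile 100). Cck, Gast and Aldh1a3 again entered through the db/db level alone. Granule genes were higher in 5 of 15, Vgf at 3.73 and Chgb at 1.96 among them, and lower in 2. The amino acid and integrated stress response differed from the late comparison, with the glutathione-degrading enzyme gene Chac1 at 2.18 and Cebpb at 1.17, a gene at least 5-fold higher in another class, higher and Atf5 at -1.24 and Vldlr at -1.01 lower, out of 15 (median 0.10, percentile 95.2). Mitochondrially encoded genes were lower in 4 of 12, mt-Nd3 at -1.45 among them (median -0.86, -0.34 with all UMIs as denominator, percentile 0). Of 31 proteasome genes 23 lay above 0 with none 2-fold apart (median 0.22, percentile 97.0). Endoplasmic reticulum genes were higher in 2 of 26, Creld2 at 1.56 and Dnajc3 at 1.15, and lower in 1, Ero1lb at -2.25.

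Together 231 genes were at least 2-fold higher and 712 lower of 4256. The median of all genes was -0.24, against 0.22 with all UMIs and 0.11 with TMM, so that 24.5%, 84.7% and 75.7% of the genes this far apart were higher. Of the 231 higher and 712 lower genes, 231 and 249 stayed at least 2-fold apart under the 3 scalings. Here too both other scalings raise every ratio, so only lower genes could drop out. Medians of the tRNA synthetase, cholesterol, interferon and apoptosis lists changed sign between scalings.

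Late against early db/db compares 98 with 70 days within diabetic mice. Fewer genes of beta-like cells lay apart here than against the control, with 7 at least 2-fold higher in late db/db and 21 lower of 3455. Genes of the amino acid and integrated stress response lay lower at the later age in 12 of 13 cases, led by Chac1 at -1.35 (-1.48 to -1.23), the translation regulator gene Eif4ebp1 at -1.25 (-1.36 to -1.15), Cebpb at -0.99 and Nupr1 at -0.95 (median -0.57, -0.50 relative to all genes, percentile 0). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at -1.22 (-1.33 to -1.11), the sulfotransferase gene Sult1d1 at -1.28 and Slc5a10 at -1.05, and of these Cdkn1a is at least 5-fold higher in another class. Higher in late db/db were Lars2, the mitochondrial leucyl-tRNA synthetase gene, at 1.86 (1.76 to 1.97), the nuclear RNA Malat1 at 1.11 and the RNA polymerase subunit gene Polr2l at 1.07.

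Gast stood at 0.94 and Cck at -0.30, and the chaperone gene Hyou1 at 0.92 in a list of 26 endoplasmic reticulum genes with 19 above 0 (median 0.10, percentile 99.5). Of 31 proteasome genes 26 lay at or below 0 (median -0.21, percentile 0.44). Beta cell transcription factors had a median of 0.16 over 9 genes and granule genes 0.14 over 14, with none of either 2-fold apart. Ins1 and Ins2 stood at -0.39 and -0.38, Iapp at -0.25, Gcg at -0.86, Sst at -1.86, Ppy at -0.03 and Pyy at -0.12.

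Of the 21 lower genes, 17 were at least 5-fold higher in another cell class than in beta-like cells. Without all such genes the count was 9, with 5 higher and 4 lower. The median of all genes was -0.07, 0.13 with all UMIs and -0.10 with TMM, with 25%, 61.5% and 33.3% of the genes 2-fold apart higher. Between scalings, which also change the genes that enter, the medians changed sign for several lists. These were glucose sensing, dedifferentiation, tRNA synthetase, antioxidant, oxidative phosphorylation, glycolysis, carbohydrate response, cholesterol, apoptosis, autophagy and immediate early genes.

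The intervention against late db/db, both at 98 days, compares db/db mice with and without the intervention. Beta-like cells with the intervention held more message of several genes that were low in late db/db, and less Gast. Slc2a2 stood at 175 CPM against 39.4, a log2 ratio of 2.15 (2.06 to 2.24), Mafa at 106 against 32.8 CPM, or 1.69, and Ins1 at 1.54. Slc30a8 stood at 1.56, the glucose-6-phosphatase gene G6pc2 at 1.44 and Sytl4 at 1.34. Gast stood at 171 CPM against 654, or -1.94 (-1.97 to -1.90), while Cck and Aldh1a3 were nearer late db/db at -0.64 and -0.47.

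Further genes with large positive ratios were the signalling regulator gene Rgs2 at 1.61, the insulin receptor-related gene Insrr at 1.47, Prss53 at 1.43 and Galnt18 at 1.42. Lower were Hap1 at -1.17, Tm4sf20 and Amigo2 at -1.09, Zcchc12 at -1.05, Polr2l at -1.02 and the metallothionein gene Mt3 at -1.01. Immediate early and heat shock genes, which tissue dissociation induces, lay below 0 in all 14 measured cases, with 3 at least 2-fold lower, Fos at -1.30, Klf6 at -1.27 and Fosb at -1.09 (median -0.63, -0.62 relative to all genes, percentile 0). Endoplasmic reticulum genes lay lower in 22 of 26, with the chaperone genes Dnajb9 at -0.87 and Hspa5 at -0.79, although Ero1lb stood higher, at 961 against 482 CPM (median -0.21, percentile 0.08). Carbohydrate response genes lay higher in 5 of 6, led by the thioredoxin-interacting protein gene Txnip at 1.02 (median 0.46, percentile 99.98). Stmn1, the one measured cell cycle gene, stood at 3.31 (3.07 to 3.55), with 83.6% of its intervention UMIs in 59 beta-like cells of clusters 9 and 33, where late db/db had 2 cells. Without these clusters it stood at 1.24 (0.92 to 1.56). Cdkn1a stood at 1.08. Stmn1 and Cdkn1a, like Fos, Klf6 and Fosb, were at least 5-fold higher in another class.

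Glucose sensing and exocytosis genes were at least 2-fold higher in 4 of 14 and lower in 0, with a median of 0.19 (percentile 99.7) that was -0.05 with all UMIs as denominator but stayed above the median of all genes, by 0.20 and 0.16. Beta cell transcription factors lay above 0 in all 10 cases (median 0.18, percentile 98.95), and their median was -0.03 with all UMIs but stayed above that of all genes, by 0.20 and 0.19. Of 5 dedifferentiation markers 4 were lower and Gast alone by 2-fold (median -0.47, percentile 0.525). Ins2 stood at 0.13, and at -0.07 with all UMIs as denominator, Iapp at 0.32, and Gcg, Sst, Ppy and Pyy at 0.99, 1.74, -0.23 and 0.47, with Sst at -0.46 when each library was clustered alone.

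In this comparison 30 genes were at least 2-fold higher and 17 lower of 3448. The median of all genes was -0.01, -0.21 with all UMIs and -0.05 with TMM, and 63.8%, 34.6% and 62.5% of the genes so far apart were higher. Of the 30 higher and 17 lower genes, 19 and 17 stayed at least 2-fold apart under all 3. Both other scalings reduce every ratio of this comparison, so only higher genes could drop out. Between scalings the medians of granule, mitochondrially encoded, cholesterol, fatty acid oxidation and autophagy genes also changed sign.

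The intervention against control shows what differed from the control in treated db/db mice of the same age. Measured dedifferentiation markers lay above the control with the intervention as well, with Cck at 14.25 (12.39 to 17.29), Aldh1a3 at 6.99 (6.67 to 7.34), Gast at 6.46 and Cd81 at 3.21. All 5 measured of the 10 listed were at least 2-fold higher (median 6.46, percentile 100). Cck, Gast and Aldh1a3 entered through the intervention level alone, as they had through that of late db/db. Mafa stood at -3.36 (-3.40 to -3.32), Slc2a2 at -2.42 (-2.45 to -2.38), Trpm5 at -4.57, Sytl4 at -2.21 and Slc30a8 at -1.83. Ins1 stood at -1.24, Ins2 at -0.85 and Iapp at 1.25, and Gcg, Sst, Ppy and Pyy at -0.78, -0.63, 0.78 and 0.52. Other genes far above the control were Pianp at 9.50, Csn3 at 7.58, C1qtnf1 at 7.10, Ankrd34b at 6.31 and the thyroxine-binding globulin gene Serpina7 at 5.38. H2-Q2 stood at -9.99 (-11.62 to -8.77) on 5 intervention UMIs, Npy at -8.69, Siglec1 at -8.51, Fam151a at -3.93, Adam32 at -3.58 and Cox6a2 at -3.52.

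Of 10 transcription factor genes 2 were lower, Mafa and Neurod1 at -1.10. Their median was -0.65 (-0.31 relative to all genes, -0.30 with all UMIs as denominator, percentile 0.49). Of 18 glucose sensing genes 6 were lower (median -0.76, -0.30 with all UMIs as denominator, percentile 0.01). Granule genes were higher in 7 of 15, with Vgf at 4.16 and the secretogranin gene Scg2 at 1.47. Txnip at 2.01 and Arrdc4 at 2.52 were higher and Acly at -1.25 lower among 6 carbohydrate response genes. Mitochondrially encoded genes were lower in 4 of 12, mt-Nd3 at -1.85 among them (median -0.62, -0.10 with all UMIs as denominator, percentile 0.02). All 12 measured tRNA synthetase genes lay below 0, Gars at -1.14 among them (median -0.67, percentile 2.75).

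There were 179 genes at least 2-fold higher than in the control and 345 lower of 4174. The median of all genes was -0.34, 0.11 with all UMIs and -0.06 with TMM, with 34.2%, 88.0% and 79.0% of the genes 2-fold apart higher. Of the 179 higher and 345 lower genes, 179 and 105 stayed at least 2-fold apart under all 3. Both other scalings raise every ratio here, so only lower genes could drop out. Medians of the amino acid, oxidative phosphorylation, proteasome, glycolysis, interferon, NF-kappaB, apoptosis and immediate early lists changed sign under another scaling.

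**Figure D2:**
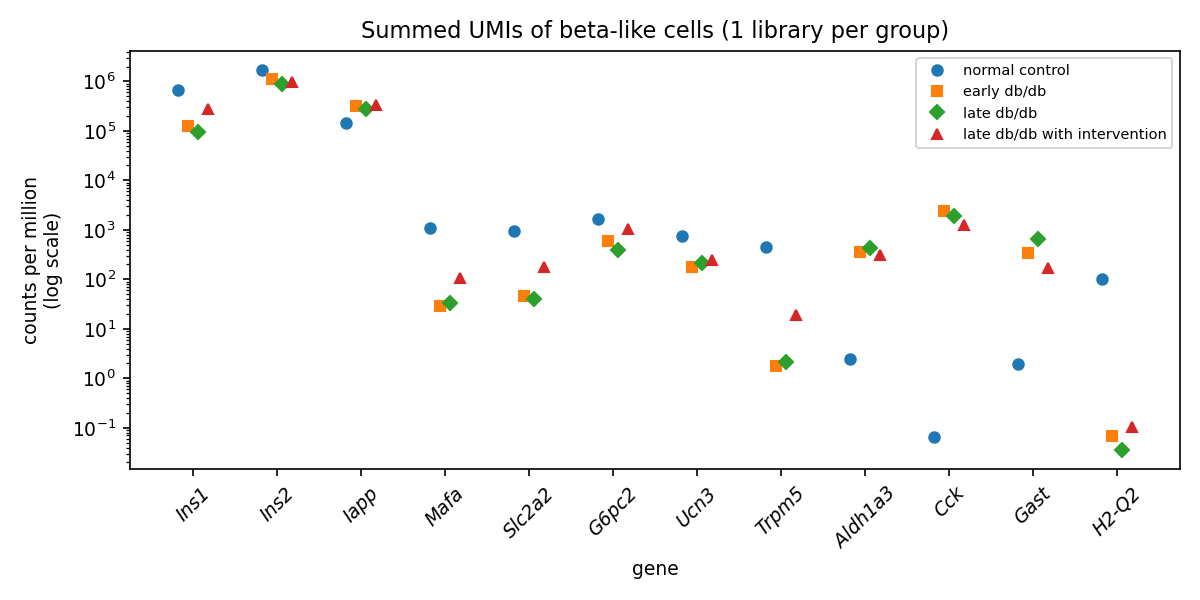
CPM on a log axis (vertical) of 12 genes in the summed beta-like cells of the 4 libraries, 1 point per library and without error bars. Mafa lies at 1087 CPM in the control, 32.8 in late db/db and 106 with the intervention, and Cck at 0.0637, 1931 and 1240.

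Most genes that set late db/db apart from the control lay nearer late db/db with the intervention. Of 683 genes at least 2-fold apart between random parts of the control and late cells, 55 (8.05%) lay nearer the control, although 544 were shifted toward it, and the median share of the distance left was 0.824. The median left was 0.933 for genes higher in late db/db and 0.793 for genes lower there. The split of cells removes counting error only. Features of the late library alone also enter the choice of genes, and could give a shift toward the control. Features of the control library alone, such as a strain difference, enter it as well. They could keep the intervention near late db/db, so the share nearer the control may be biased in either direction. No other scaling was tried for the position. On the same log2 scale, from whole libraries and without a pseudocount, G6pc2 covered 68.2% of the distance from late db/db to the control, Ins1 55.4%, Slc2a2 47.0%, Slc30a8 46.0%, Mafa 33.5%, H2-Q2 13.2% (on 5 intervention UMIs), Ucn3 8.38% and Siglec1 2.26% (on 8).

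Shares of beta-like cells with a UMI, after thinning each cell to 3000 UMIs, mostly followed the summed levels. Aldh1a3 was seen in 0.0903% of control cells (0.0109 to 0.326), 28.1% in early db/db (25.9 to 30.5), 35.8% in late db/db (32.5 to 39.3) and 25.2% with the intervention (23.7 to 26.7). Mafa was seen in 54.0%, 3.25%, 3.02% and 11% of cells and Slc2a2 in 51.6%, 4.88%, 4.15% and 17.2%. Ucn3, a marker of mature beta cells, was seen in 44.2%, 16.3%, 20% and 21.5%. Endothelial-like cells, which should lack these genes, showed Aldh1a3 in 0%, 0.344%, 1.89% and 6.41%, Mafa in 6.59%, 0.687%, 0% and 0.641%, Slc2a2 in 4.95%, 0.344%, 0% and 1.28%, and Ucn3 in 3.30%, 0.344%, 0% and 3.85%. Macrophage-like cells showed Aldh1a3 in 0%, 1.34%, 0.962% and 5.80%, Mafa in 3.95%, 0%, 0% and 2.90%, Slc2a2 in 5.26%, 0%, 0% and 0%, and Ucn3 in 3.95%, 0%, 0% and 2.90%.

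Unthinned, the shares in beta-like cells were 1.55%, 83.6%, 91.9% and 76.3% for Aldh1a3, 95.7%, 20.9%, 25% and 48.0% for Mafa, 96.4%, 40.6%, 44.6% and 65.7% for Slc2a2 and 95.3%, 75.7%, 88.0% and 79.3% for Ucn3. Median depths before thinning were 8355, 3955, 8033.5 and 4093.5 UMIs in endothelial-like and 10450, 6419.5, 9367 and 5168 in macrophage-like cells, and shallower beta-like cells left out numbered 47, 19, 21 and 90. The proliferation marker Mki67 was seen in 0.722%, 0.271%, 0.252% and 1.54% of thinned beta-like cells and in 2.63%, 3.36%, 6.73% and 2.90% of macrophage-like cells. The late beta-like value rested on 2 of 795 cells (0.0305 to 0.906). Unthinned, the beta-like shares were 2.74%, 2.48%, 5.02% and 5.39%, so the order of late db/db and control turned with the thinning. Gcg, Sst and Ppy were seen in 38.4%, 14.0% and 43.9% of late beta-like cells against 51.9%, 20.8% and 43.4% of late endothelial-like cells. In the other 3 libraries their shares were lower than in endothelial-like cells. Thinning keeps a smaller part of a beta-like cell, with late medians of 87721 UMIs against 9423.5 in endothelial-like cells. These shares therefore do not decide between background and message of the beta-like cells.

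**Figure D3:**
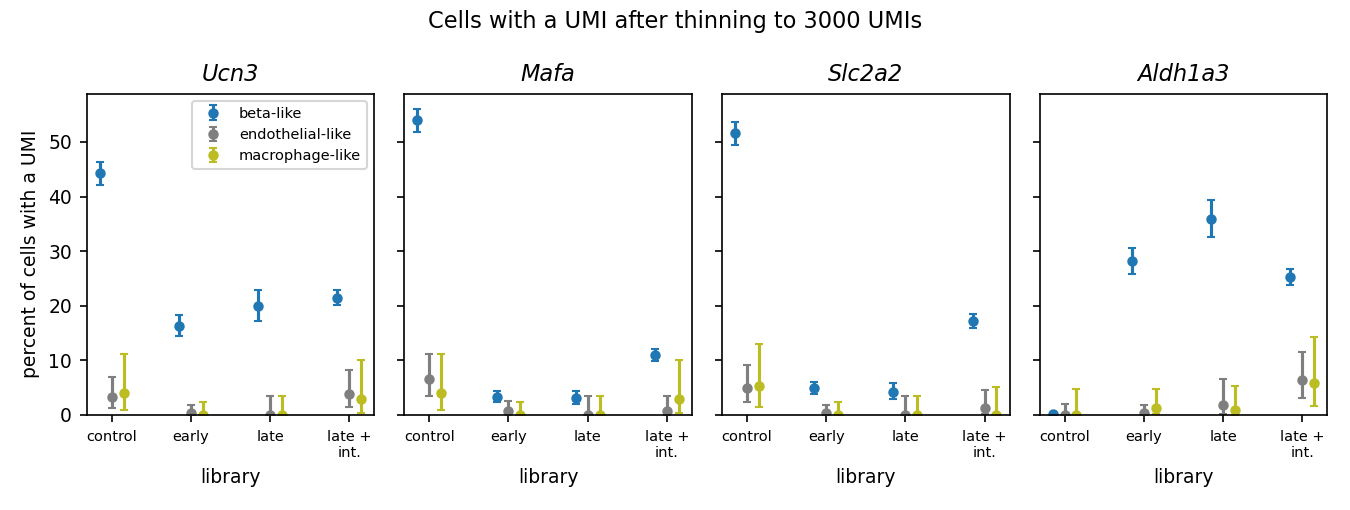
Percent of cells with at least 1 UMI (vertical axis) of Ucn3, Mafa, Slc2a2 and Aldh1a3 after thinning to 3000 UMIs, in beta-, endothelial- and macrophage-like cells of the 4 libraries, with exact 95% intervals as lines. In beta-like cells Mafa is seen in 54.0% of control and 3.02% of late db/db cells, and Aldh1a3 in 0.0903% and 35.8%.

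Alpha-like cells held more Ppy and Pyy, genes of the pancreatic polypeptide family, in the db/db libraries. Ppy took 1.11% of alpha-like UMIs in the control, 7.08% in early db/db, 6.98% in late db/db and 4.86% with the intervention, and Pyy 1.95%, 8.62%, 8.54% and 6.36%. Gcg took 33.6%, 32.2%, 27.4% and 28.6%. As background, Ppy was seen in 51.6%, 38.5%, 43.4% and 85.3% of thinned endothelial-like cells in the same order. Against the control, late db/db had 51 genes at least 2-fold higher and 31 lower of 3376, early db/db 77 and 68, and the intervention 45 and 27. Pianp stood at 7.14, the uroplakin gene Upk3a at 2.25, the complement inhibitor gene Cd59a at 2.23 and the parathyroid hormone-related gene Pthlh at 2.21 in late db/db against control. The thymosin gene Tmsb15b1 stood at -7.38 and the kinase gene Mapk15 at -3.43, and H2-Q2 had 1461, 1, 0 and 0 UMIs. Gamma cell markers were raised in alpha-like clusters 0 and 1, so gamma cells within them were not set apart. Late against early db/db had 17 genes higher and 26 lower, Lars2 at 2.55 and the activity-dependent gene Npas4 at -1.83 among them. The intervention against late db/db had 23 higher and 35 lower, with the clock gene Nr1d2 at 1.29 and Fos at -1.27. Most alpha-like cells were in cluster 0 in the control, late and intervention libraries (1081, 129 and 579 cells) and in cluster 1 in early db/db (599).

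Delta-like cells showed some of the same differences. Late db/db against control had 70 genes higher and 36 lower of 4099, with Pianp at 4.30, the synaptic organiser gene Cbln4 at 2.94, Sorl1 at 2.63 and Cd59a at 2.29, and Rnaset2b at -6.12 and Olfm3 at -2.43. Early db/db had 84 and 67 and the intervention 46 and 37, the dynorphin gene Pdyn at 2.15 among the latter's higher genes. H2-Q2 had 386 UMIs in the control and 0, 0 and 1 in the others. With the intervention against late db/db, 15 genes were higher and 39 lower, Fosb at -2.07, the heat shock gene Hspa1b at -2.05 and Fos at -1.96 among them. Late against early db/db had 17 higher and 29 lower, with the nuclear RNA Malat1 at 1.06. Sst took 12.8%, 14.9%, 14.9% and 16.8% of delta-like UMIs. Gamma cell markers were also raised in cluster 7, which held all delta-like cells, so gamma cells within it were not set apart. These ratios rest on 160 alpha-like and 134 delta-like cells in the late library.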

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

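Gene groups in barcodes that failed the cell filter, which no comparison uses, were examined only after the data were seen, and the level in the control library served as the reference. Acinar genes, which encode digestive enzymes of the exocrine pancreas, made up 23.4% of the UMIs in such barcodes of early db/db, 6.43% in late db/db and 0.402% with the intervention, against 0.257% in the control. Haemoglobin genes of red cells made up 4.29% in early db/db, 4.89% in late db/db and 23.2% with the intervention, against 3.27% in the control. These are shares of summed UMIs in 1 library per group, with 1514 such barcodes in the control, 1855 in early db/db, 861 in late db/db and 1685 with the intervention.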

How the results depend on the processing

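Automatic doublet thresholds, leaving out beta-like clusters of very high UMIs, counts that need 2-fold in all 3 scalings, and endocrine cells as denominator were chosen after seeing the data. Of the alternative values of the beta-like shares and gene counts, 60 stayed within the interval or within 1.5 times the count and 59 moved; where no reason is given, the cause was not tested. The order of the beta-like shares of all kept cells (intervention, control, early, late) held under each alternative filter and clustering, except that without a cell filter the control, at 58.6%, stood above the intervention at 56.4%, with early db/db at 24.6%. The shares of the control, early db/db and intervention were 53.8%, 34.8% and 70.8% with the stricter filter, and 46.8%, 34.7% and 67.4% with doublets kept. Those of the control and early db/db were 52.9% and 30.8% at resolution 0.5, 53.9% and 36.1% with each library clustered alone and 53.2% and 30.1% with 4000 variable genes, and early db/db was 35.2% at resolution 2. Automatic doublet thresholds gave 48.0%, 35.6%, 14.9% and 67.5% in the 4 libraries. Gene counts follow in the order late, early and intervention against control, late against early db/db, and intervention against late db/db. TMM gave 248, 354, 205, 12 and 16 genes, and all UMIs as denominator gave 399, 250, 13 and 26 for the last 4. A minimum of 10 CPM gave 1658, 2241, 1265, 76 and 176, a minimum of 200 CPM 179, 235, 154, 5 and 13, and no low-count filter 6536, 6870, 4944, 3042 and 3357, since each changes how many genes enter. A threshold of 1.5-fold gave 1695, 1947, 1646, 89 and 217, and 3-fold 239, 308, 172, 16 and 11, by construction. Requiring 2-fold in all 3 scalings gave 317, 480 and 284 against the control. These are counted among the 676, 943 and 524 genes of the first denominator, so the count can only fall. The counts with TMM and with all UMIs apply the minimum of 50 CPM anew, so they can be smaller than these. Late against early db/db gave 51 genes with thinned cells and 9 without genes at least 5-fold higher in another class. Without low-count filter 54.5% of the genes in late db/db against control were higher, against 27.8%. Of the ratios of named genes, 4829 values stayed within the counting interval, 2002 moved, and 5 that had been at least 2-fold apart changed sign, all of hormones of other islet cells. Ppy in late db/db against control was -0.76 with the stricter filter and -0.0345 with libraries clustered alone, and in early db/db against control -0.79 with the stricter filter. Sst in the intervention against late db/db was -0.46 with libraries clustered alone, and Gcg in late db/db against control was 11.50 after free RNA was subtracted. The Gcg value measures no fold, since the subtraction took away nearly all Gcg of the control. Of list medians 1238 values stayed within 0.2, 252 moved, and 2 that had been outside the central 95% of random lists changed sign with all UMIs as denominator in the intervention against late db/db, beta cell transcription factors to -0.0267 and glucose sensing and exocytosis to -0.0546. Counting values of any size, 84 of 6836 gene ratios and 114 of 1492 list medians changed sign, 33 and 37 of them with all UMIs as denominator. That denominator shifts all gene ratios of a comparison alike, but it also changes which members of a list enter its median. With endocrine cells as denominator the order was intervention at 79.6%, late db/db at 73.5%, control at 58.4% and early db/db at 56.5%. The position was 7.11% of genes nearer the control from whole libraries and 9.32% at 1.5-fold, against 8.05%. Thinning to 3000 UMIs per cell limits the shares of cells with a UMI, where 59 of the alternative values moved and 5 did not.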

Other observations

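All tests in this part except that of library batch were chosen after the result was seen. Vessel cells differed between the libraries as well. Endothelial-like cells of late db/db held genes of high endothelial venules, the vessels through which lymphocytes enter lymph nodes, with 49904 UMIs of Glycam1, which had 0 in the other 3 libraries, and 2462 of Madcam1 against 0 in the control, 99 in early db/db and 16 with the intervention. Lyve1, a lymphatic vessel marker, had 1302 UMIs against 3 in the control, a log2 ratio of 9.33 (7.78 to 11.61). Clusters 12 and 13, with 21 and 24 endothelial-like cells, were found in late db/db alone. In early db/db against control the retinoic acid hydroxylase gene Cyp26b1 stood at 6.65 (5.89 to 7.52), Tmem252 at 6.75, the leucine-rich glycoprotein gene Lrg1 at 4.31 and the von Willebrand factor gene Vwf at 6.57 (4.70 to 9.63) on 2 control UMIs. With the intervention Cyp26b1 stood at 6.73 and Tmem252 at 6.56 against the control, and the interferon-induced gene Isg15 at -2.77. Most endothelial-like cells of the control were in cluster 8 (166) and most of early db/db and the intervention in cluster 11 (425 and 220).

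Macrophage-like cells of late db/db, compared with early db/db, held more Ctsk, which encodes the protease cathepsin K, at a log2 ratio of 8.26 (6.71 to 10.54) on 3 early UMIs. The cystatin gene Cst7 stood at 6.98 (4.48 to 12.30) on 1 early UMI. Retnla, a marker of alternatively activated macrophages, had 0 UMIs in late db/db against 418 and was at least 155-fold lower, and the monocyte chemokine gene Ccl2 stood at -4.11 (-4.81 to -3.49) and Lyve1, which also marks resident macrophages, at -3.58. Of the genes that entered, 289 were at least 2-fold higher and 209 lower, from 121 late and 184 early cells. Cluster 6 held 41.3% of the late macrophage-like cells (50) and 3.26% of the early (6), and cluster 5 the rest. The ratios were taken over both clusters together, so this difference in makeup may enter them.

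Lymphocytes were 66.0% of the late db/db cells (64.8 to 67.2), against 0.516% in the control, 7.93% in early db/db and 0.652% with the intervention. Free RNA was argued against only weakly, since lymphocyte markers in late beta-like cells reached 0.408% of their level in lymphocytes. That level is per UMI. Late beta-like cells had a median of 86868 UMIs against 3635 in B-like and 6272 in T- and NK-like cells, so depth alone lowers it. Lymph node tissue carried into the library may be the source: 61.8% of 251 late stromal cells (55.4 to 67.8) held at least 2 of 12 listed lymph node stroma genes, against 0.957% in the control, with Ccl21a at 74666 UMIs and Ccl19 at 7238 in late fibroblast-like cells. Of the 12 genes 5 had already been seen in these cells, control fibroblast-like cells also held Ccl19 (58 UMIs), Pdpn and Il7, and lymphoid tissue formed inside the pancreas would give the same result. Immune cells gathered in or beside the islets stay open, since interferon and MHC class I genes in beta-like cells had a median log2 ratio of late over early db/db of -0.0687, which excludes nothing.

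In beta-like cells 16 genes lay far from the control in every db/db library. RNA of other cell types stays open for part of them: 2 of the 16 (12.5%, interval 1.55 to 38.4), Spp1 and Basp1, were at least 5-fold higher in another class, and Npy and Cd24a fell just short at log2 2.25 and 2.29, whereas the highest other class lay below beta-like cells for Cck (-3.27), Aldh1a3 (-2.61), Trpm5 (-2.75) and Gast (-1.93). A strain variant may be a candidate source, as H2-Q2, Pianp and Spp1, 3 of the 5 genes measured in alpha-like cells (60%, interval 14.7 to 94.7), were at least 4-fold apart there too and Serpina7 and Basp1 were not. In delta-like cells 4 of 10 measured genes were (40%, interval 12.2 to 73.8), namely Pianp, Aldh1a3, Cck and H2-Q2, and Cck also in endothelial-like cells. Ins2 took up to 8.60% of delta-like UMIs, so RNA of beta cells is open there. In control alpha-like cells H2-Q2 stood at 117 CPM with Ins2 at 0.919% of UMIs, so RNA of beta cells gives little of it. Outside the 16 genes, Rnaset2b had 926 UMIs in control delta-like cells against 10 in early db/db, 5 in late db/db and 0 with the intervention. In endothelial-like cells it had 169 against 1, 2 and 0. Rnaset2b was picked by its large ratio, and these few genes do not decide. The diabetic state of beta cells was not tested separately and stays open.

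Levels of several beta-like genes of the intervention library lay between late db/db and control. Control cells mixed into that library were argued against, since H2-Q2 stood at 0.0983% of its control level (upper limit 0.229%, from 5 UMIs), while on the linear CPM scale, on which mixed cells add, Ins1 covered 32.5%, Slc2a2 15.1% and Mafa 6.95% of the distance to the control. Free RNA cannot be told apart for the genes as a set. The level in endothelial- and macrophage-like cells was a median of 73.6% of the excess over late db/db for 23 genes (quartiles 23.1 and 170.3). That is an upper bound, since those cells had medians of 4093.5 and 5168 UMIs against 41378 in beta-like cells. The level was 12.4% for Slc2a2, from 10 UMIs in those cells, 9.87% for Trpm5, from 1 UMI, 19.0% for G6pc2 and 25.1% for Mafa. It was 220.8% for Neurod1 and 323.4% for Nkx2-2. Library batch cannot be told apart from the intervention with 1 library per group. An effect of the intervention stays open and was not tested separately.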
